A study of Mus musculus with 15 samples.

How the data were processed

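Total RNA from mouse knee joint synovium was labelled with biotin and hybridized to Affymetrix arrays, 1 per sample, per the labels' protocols. The deposited table holds the intensity signal of 45101 probe sets on 15 arrays, computed with MAS5 per the submitters' processing notes; the MAS5 version is not given in the sources used here. The deposited intensity values are linear, and their mean after trimming 2% at each end lay between 149.9 and 150 on every array, so the arrays were taken as scaled by the authors. No further scaling was applied in the main setting.

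Groups were taken from the sample titles and source names: healthy naive, and CIA with no, mild, moderate or severe swelling, 3 arrays each. The source names give the degree of swelling, and the titles give the same grades as joint inflammation. The arrays without swelling are thus titled as having no joint inflammation. Signals were transformed to log2(signal + 16), so fold changes of dim genes are understated. Probe sets were named through GEO's platform annotation, which can be old and lists 35890 of the probe sets, 34958 with 1 gene symbol and 932 with several; 9211 were unnamed here. Of those with 1 symbol, 34754 matched a RefSeq gene table, used for names only, and 0 symbols changed. No gene was named from a probe set with several symbols. Each of the 18193 named genes was represented by the probe set with the highest mean, and 14309 genes were tested, those above the array's own 40th percentile on at least 3 of the 15 arrays. Of 4114 genes called between severe swelling and naive that have several probe sets, 235 had another probe set called in the opposite direction.

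The model was fitted in R 4.3.3 with limma 3.58.1, as group means over all 15 arrays (10 residual and 5.56 prior degrees of freedom), with empirical Bayes moderation along an intensity trend. The comparisons were each CIA group against naive, severe against no swelling, each adjacent step of swelling, a linear slope with scores from 0 to 3 over the 4 CIA groups, and a moderated F test of any difference among the 5 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided, and SE values are those of limma. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1. The 39 gene lists, with members chosen for joint tissue, immune cells and the other cell types a dissection can hold, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, for the comparisons with naive and the slope. Members were also adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. Some genes are members of more than 1 list.

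Named genes followed a rule. It took the 12 highest and 12 lowest log2 fold changes in severe swelling against naive among called genes whose groups did not overlap, the 6 highest and 6 lowest in the other comparisons with naive, in severe against no swelling and for the slope (there without the overlap condition), and the 3 highest and 3 lowest for each adjacent step, or the 3 lowest p-values where no gene passed. It added up to 3 members of each list with the lowest p in severe swelling and a fixed panel, of which Tnfrsf11b, Nos2 and Ido1 lay below the signal filter and Ddx3y had no probe set with a single symbol in the annotation used. Members named because they moved against their list, or to complete a count of 5 or fewer, were chosen after their values were seen. The groups, tests, lists, rule and all but 2 of the alternative settings were fixed before the data were examined.

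The settings tried as alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, array medians aligned, the mean of a gene's probe sets, every probe set by itself, no intensity trend, only the groups compared, the replicate number as a block, array quality weights, and leaving out each array in turn. Scaling on the geometric mean of 9 hybridization control probe sets and array quality weights estimated gene by gene were added after seeing the data. On simulated data for severe swelling against naive over 14309 genes, the same steps recovered 10% of 50 genes shifted by 0.5 on the log2 scale, 68% of 50 shifted by 1, and 100% of 50 shifted by 2 and of 50 shifted by 3, with 6.75% false calls. For no swelling against naive over 14309 genes they recovered 12%, 86%, 100% and 100%, with 8.19% false calls. These values depend on the random draw: over 10 further draws, recovery at a shift of 1 was 56% to 80% in each comparison, and false calls were 3.16% to 7.1% for severe and 3.18% to 9.09% for no swelling against naive. In each of the first 2 tests 1 of 39 lists was called, the shifted one. The simulated genes varied independently and few of them were changed. The simulation therefore does not show how the list test or the false calls behave on the measured arrays, where genes move together. There, a split of the moderate and naive arrays across their groups called 23 lists with 0 genes called. Shared control arrays were simulated with 20 sets of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.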

Results

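Messenger RNA of mouse knee joint synovium was measured on 15 arrays, in 5 groups of 3. Collagen-induced arthritis (CIA) is a model of inflammatory arthritis in which mice are immunized against type II collagen, here with 100 µg in adjuvant on day 0 and a boost of 100 µg on day 21. The CIA samples form 4 groups by the degree of joint swelling (none, mild, moderate or severe), and 1 group is named healthy naive. The protocol text of the naive samples names the same immunization and was read as written for the series as a whole; if it did apply to them, every comparison with naive would have another meaning. Median signals ranged from 36.3 to 47.6 intensity units per array, and the number of arrays limits the precision of every value. Nothing in the labels says that replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical. The first principal component held 70.2% of the variance. Its means were -63.8 in naive joints, -54.9 without swelling, 15.6 with mild, 50.6 with moderate and 52.6 with severe swelling. It parted swollen from other arrays, but not naive from no swelling or moderate from severe. No-swelling replicate 3 (-68.3) lay below every naive array (-66.3 to -62.1), and moderate arrays (44.9 to 55.9) lay within the severe range (41.4 to 62.7). Mild replicate 2 lay apart from its group on this component, at -7.34 against 18.5 and 35.7.

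The comparison of severely swollen with naive joints asks which genes differ when inflammation is strongest. The 12 largest increases included alarmins, proteases of tissue breakdown and a chemokine. Mmp13, a collagenase of cartilage breakdown, had a signal of 3.67 ± 3.19 (SD, n = 3) in naive and 3135 ± 902 in severely swollen joints, a log2 fold change of 7.29 ± 0.73 (SE) that was 9.6 with a pseudocount of 1 and 5.52 with 64. S100a9 and S100a8, the subunits of calprotectin, rose by 7.14 ± 0.48 and 6.73 ± 0.54. The acute-phase protein gene Saa3 rose by 6.60 ± 0.29, Cxcl5, a chemokine that draws neutrophils, by 6.4 ± 0.21, and the protease inhibitor gene Slpi by 6.30 ± 0.34. The other genes among the 12 largest increases were Mmp3, Mpeg1, Cthrc1, Chil1, Mfap4 and Timp1, with log2 fold changes between 5.17 and 5.51. The largest decreases were in muscle genes: Myl3 (-4.46 ± 0.67) and Myl2 (-4.43 ± 0.76), which encode slow-fibre myosin light chains, Myh7 (-4.11 ± 0.88) and Myh2 (-3.57 ± 0.74), which encode myosin heavy chains, and Perm1 (-3.91 ± 0.36), a regulator of muscle mitochondria. Dhrs7c, Smox, Lrrc38, Fbp2, Nmrk2, Mlf1 and Tlcd3b completed the 12 largest decreases (as with the increases, chosen among called genes whose groups did not overlap), with log2 fold changes from -4.13 to -3.51. The mean naive signals of Mmp13, S100a9 (17.3), S100a8 (21.7) and Cxcl5 (4.47) lay under the naive arrays' 40th percentile of 25.8 to 28.3, so the pseudocount sets the size and rank of their changes.

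**Figure D1:**
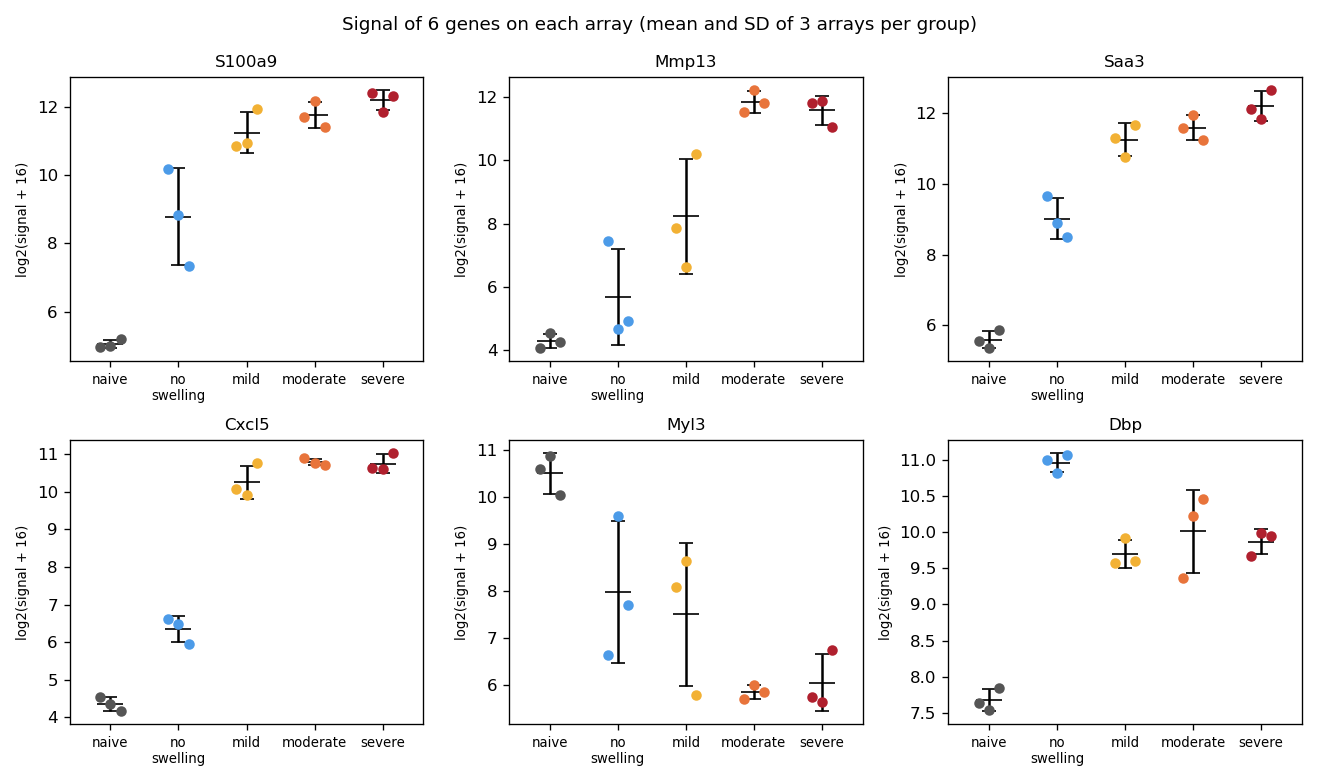
Log2(signal + 16) of 6 genes (vertical axes) on each array (points) in the 5 groups (horizontal axes), with the mean (long line) and SD (bars) of 3 arrays. S100a9, Saa3 and Cxcl5 rise from naive to swollen joints, Mmp13 is highest in moderate and severe swelling (mean signals 3751 and 3135), Myl3 lies lower in the CIA groups, and Dbp is highest without swelling (mean signal 1983).

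Inflammatory mediators and receptors rose together in severe swelling. Among 13 measured proinflammatory cytokine genes, 9 rose (9 also when adjusted over the list alone), among them Il6 (4.38 ± 0.34), Il1b (4.0 ± 0.25) and Tnfsf11 (3.08 ± 0.29), which encodes the osteoclast factor RANKL. Il12a fell (-1.34), and 3 did not pass, including Tnf at 0.65 ± 0.46 (adjusted p = 0.249 with limma, signals of 7.27 and 22.1). The cytokine list's adjusted p was 0.00131 with the preset correlation, and the adjusted p = 0.24 with an estimated correlation. Of 12 cytokine antagonists and anti-inflammatory genes, 10 rose (10 adjusted over the list alone), such as Arg1 (4.38 ± 0.34), Socs3 (3.71 ± 0.20) and Il1rn (0.96 ± 0.20), while Tsc22d3, a glucocorticoid-induced gene, fell (-0.79). 20 of 23 chemokine genes rose (20 adjusted over the list alone) and none fell, including Cxcl1 (3.53 ± 0.22), Ccl12 (3.43 ± 0.30) and Ccl2 (3.01 ± 0.46). Toll-like receptor and inflammasome genes rose in 13 of 15 cases (13 adjusted over the list alone), for example Tlr2 (2.64 ± 0.26) and the adaptor gene Myd88 (2.23 ± 0.17). All 11 measured genes of Fc gamma receptor signalling rose (11 adjusted over the list alone), among them Tyrobp (3.95 ± 0.33) and Fcer1g (3.27 ± 0.33), and 11 of 12 leukocyte adhesion genes did (11 adjusted over the list alone), among them Selp (3.96 ± 0.22) and Vcam1 (3.57 ± 0.22). For these 5 lists the adjusted p lay between 6.82e-07 and 0.00359 with the preset correlation, and for each the adjusted p = 0.24 with an estimated correlation.

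Markers of myeloid cells were higher, whereas lymphocyte markers were mixed. 11 of 15 genes of neutrophil and monocyte alarmins and granules rose (11 adjusted over the list alone), including Csf3r (4.86 ± 0.29), Clec4d (3.87 ± 0.23) and Cxcr2 (3.08 ± 0.20). The list's adjusted p was 8.96e-06, and the adjusted p = 0.24 with an estimated correlation. None of 5 genes of marrow progenitor granules passed (0 adjusted over the list alone), with Mpo at 0.57 ± 0.36. That list had a median of 0.21, a mean of 0.04 and a test that pointed down (adjusted p = 0.868). Macrophage markers rose in 15 of 16 cases (15 adjusted over the list alone), such as Trem2 (3.61 ± 0.34), Msr1 (2.64 ± 0.24) and Cd68 (2.61 ± 0.26). Their list had an adjusted p of 1.22e-05 and an adjusted p = 0.308 with an estimated correlation. Of 11 T cell markers 5 rose, among them Cd5 (1.48 ± 0.28) and Cd3g (1.10 ± 0.28), and 2 fell, Cd27 (-1.14 ± 0.32) and Zap70 (-0.65). Counts adjusted over the list alone were the same, and the T cell list's adjusted p was 0.725. Of 9 B cell and plasma cell markers 3 rose (3 adjusted over the list alone): Sdc1 (3.83 ± 0.26), Xbp1 (1.27 ± 0.17) and Blk (0.79). Ighm fell (-2.60 ± 0.31) on the probe set used, but another of its probe sets was called higher, and the list's adjusted p was 0.419. Of 8 mast cell markers Hdc (2.94 ± 0.27) and Kit (2.01 ± 0.21) rose and Tpsb2 (-1.21 ± 0.43) fell, with the same counts adjusted over the list alone. The mast cell list's adjusted p was 0.749, and its median of 0.02 changed sign with quantile normalization (-0.13) and with aligned array medians (-0.15). Tpsb2 did not pass without naive replicate 2 or 3 or severe replicate 1 or 2 (adjusted p from 0.0559 to 0.121 with limma).

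Antigen presentation, interferon response and complement genes were also higher in severe swelling. 8 of 10 genes of MHC class II presentation rose (8 adjusted over the list alone), including Ctss (3.44 ± 0.31), H2-Aa (2.62 ± 0.40) and Cd74 (2.46 ± 0.40). Among 11 genes of the immunoproteasome and MHC class I pathway, 10 rose (10 adjusted over the list alone), such as Tap1 (1.91 ± 0.20) and Psmb8 (1.51 ± 0.18), and Psme1, a proteasome activator subunit, fell (-0.42). 11 of 12 complement genes rose (11 adjusted over the list alone), among them C3ar1 (2.90 ± 0.27), Cfb (2.38 ± 0.29) and C1qa (2.36 ± 0.31), while Cd55, which limits complement on cell surfaces, fell (-1.06). These 3 lists had adjusted p-values from 0.000769 to 0.00543, and each had an adjusted p = 0.308 with an estimated correlation. 13 of 17 interferon response genes rose (14 adjusted over the list alone), such as Oas1a (1.45 ± 0.18) and Gbp2 (1.42 ± 0.23), and the list's adjusted p of 0.0021 became an adjusted p = 0.451 with an estimated correlation.

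Genes of matrix breakdown and fibroblast matrix rose, and those of other joint tissues did so in part. All 14 measured matrix metalloproteinase and ADAMTS genes rose (14 adjusted over the list alone), with Mmp9 at 4.02 ± 0.44, Adamts4 at 3.15 ± 0.21 and Adam8 at 2.72 ± 0.20. The list's adjusted p was 8.38e-07, and the adjusted p = 0.24 with an estimated correlation. All 18 genes of fibroblast collagens and matrix did too (18 adjusted over the list alone), including Postn (3.89 ± 0.27), the collagen cross-linking enzyme gene Lox (3.72 ± 0.30) and Col12a1 (3.01 ± 0.29). The matrix list had an adjusted p of 8.22e-07 and an adjusted p = 0.308 with an estimated correlation. Protease inhibitors split, with 4 higher (Slpi, Timp1 at 5.17 ± 0.42, Serpina3n at 2.74 and Timp2 at 1.24) and 3 lower (Timp4 at -2.34 ± 0.26, Timp3 at -0.66 and Cst3 at -0.41), the same counts adjusted over the list alone, and an adjusted p of 0.494. Of 11 lining fibroblast genes 8 rose (8 adjusted over the list alone), among them Cdh11 (4.76 ± 0.39), Pdpn (3.26 ± 0.20) and Prg4 (1.88 ± 0.23), which encodes the joint lubricant lubricin. Clic5 (-2.54) and Cd55 fell. That list had an adjusted p of 0.0221 and an adjusted p = 0.24 with an estimated correlation. Cartilage genes rose in 7 of 12 cases (7 adjusted over the list alone), with Col11a1 at 3.07 ± 0.35, Acan at 3.04 ± 0.42 and Col2a1 at 2.35 ± 0.40. Osteoclast genes rose in 8 of 13 (8 adjusted over the list alone), with Ctsk at 4.37 ± 0.34, Acp5 at 3.30 ± 0.35 and Atp6v0d2 at 2.51 ± 0.21. Car2 (-1.35) and Nfatc1 (-0.46) of the osteoclast list fell. The cartilage list's adjusted p was 0.0285 and the osteoclast list's 0.0224, and each had an adjusted p = 0.308 with an estimated correlation. With no filter on low signals the cartilage list did not pass (adjusted p = 0.0957), and with the filter at the 60th percentile the osteoclast list did not (adjusted p = 0.104). None of 4 osteoblast genes rose and Alpl fell (-1.02 ± 0.26; the same adjusted over the list alone), with an adjusted p of 0.594 and a list median of -0.05 that turned to 0.13 when arrays were scaled on hybridization controls.

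Vessel, cell division and lipid mediator genes completed the groups that rose. 10 of 14 endothelial genes rose (11 adjusted over the list alone), such as Icam1 (1.57 ± 0.18) and Pecam1 (0.99 ± 0.14). The endothelial list had an adjusted p of 0.00359 and an adjusted p = 0.308 with an estimated correlation. Cell cycle genes rose in 17 of 18 cases (17 adjusted over the list alone), among them Birc5 (3.34 ± 0.28), Rrm2 (3.18 ± 0.26) and Mcm5 (2.85 ± 0.23), and the mitotic kinase gene Aurka fell (-0.51). The cell cycle list's adjusted p was 9.04e-07, and the adjusted p = 0.24 with an estimated correlation. 10 of 13 prostanoid and leukotriene genes rose (10 adjusted over the list alone), including Ptgs2 (3.96 ± 0.29), the inducible cyclooxygenase gene, and Alox5ap (3.02 ± 0.31). The lipid mediator list had an adjusted p of 0.000889 and an adjusted p = 0.308 with an estimated correlation. In the oxidative burst and antioxidant list 6 of 11 rose, among them the NADPH oxidase genes Ncf4 (3.0 ± 0.25) and Cyba (2.91 ± 0.27). The antioxidant genes Gclm (-1.01), Nqo1 (-0.85), Sod2 (-0.60) and Txnrd1 (-0.52) fell, with the same counts adjusted over the list alone and an adjusted p of 0.264.

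Genes of oxidative phosphorylation, fatty acid metabolism and fat cells were mostly lower in severe swelling, and those of muscle and glycolysis in part. All 20 measured genes of oxidative phosphorylation fell (20 adjusted over the list alone), led by Cox7a1 (-3.29 ± 0.26), Ndufs1 (-2.02 ± 0.20) and Sdha (-1.51 ± 0.15). The list had a median of -1.38, an adjusted p of 1.63e-11 and an adjusted p = 0.24 with an estimated correlation. Of 15 genes of fatty acid oxidation and lipogenesis 11 fell (12 adjusted over the list alone), among them Me1 (-1.95 ± 0.19), Acadm (-1.84 ± 0.18) and Etfdh (-1.52 ± 0.17). Acly (1.09) and Elovl6 (0.47), both of fatty acid synthesis, rose. 9 of 13 adipocyte genes fell (9 adjusted over the list alone), such as the glucose transporter gene Slc2a4 (-2.79 ± 0.26), Lpl (-1.92 ± 0.21) and Adipoq (-1.88 ± 0.50). Both lists had an adjusted p of 0.000201 and an adjusted p = 0.24 with an estimated correlation. Of 20 skeletal muscle genes 8 fell (7 adjusted over the list alone) and 12 did not pass, including Acta1, the main skeletal actin gene, at 0.10 ± 0.21 and signals of 10600 and 11590. The muscle list's median was -0.27, its adjusted p 0.0103, and the adjusted p = 0.534 with an estimated correlation. A list of 24 muscle genes drawn up after seeing the data had a median of -1.28 (20 fell and 1 rose). The medians of fatty acid and adipocyte genes were -1.05 and -1.35. A smaller amount of muscle in the dissections stays open in severe swelling, so these falls cannot be assigned to a cell type. Glycolysis genes split into 5 higher, such as Pgam1 (1.81 ± 0.20) and Hk1 (1.29 ± 0.15), and 5 lower (6 adjusted over the list alone), such as the lactate transporter gene Slc16a3 (-2.69 ± 0.27). The glycolysis list had a median of -0.20, which turned to 0.04 with scaling on hybridization controls, a mean of 0.06 and an adjusted p of 0.648. The ratio of the 3' to the 5' actin control probe sets, a sign of RNA quality, was 0.977 ± 0.0757 (SD, n = 3) in naive and 1.25 ± 0.0321 in severely swollen joints and moved with these groups, while that of Gapdh was 0.853 ± 0.0319 and 0.891 ± 0.067.

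Among the remaining lists none was called in severe swelling. Heat shock and immediate early genes split, with Junb (3.13 ± 0.20) and Fos (2.44 ± 0.23) among 8 that rose and Hspa1a (-2.12 ± 0.24), Hspa1b (-1.63 ± 0.18) and Hsph1 (-0.94) lower, the same counts adjusted over the list alone, and an adjusted p of 0.293. Of 13 clock genes 5 rose, including Dbp (2.19 ± 0.21) and Per1 (1.39 ± 0.16), and 6 fell, including Arntl (-2.20 ± 0.20), the same adjusted over the list alone. The clock median was -0.07, and 0.14 with scaling on hybridization controls, the mean was 0.11, and the test pointed down (adjusted p = 0.749). Of 10 Wnt pathway genes Sfrp1 (2.17 ± 0.35), Dkk3 (2.03 ± 0.32) and Sfrp2 (1.47), all of secreted antagonist families, rose, and Frzb (-1.49 ± 0.22), another antagonist, and Wnt5a (-0.69) fell, with the same counts adjusted over the list alone. The Wnt list's median was 0.01, and -0.12 with quantile normalization and -0.15 with aligned medians, its mean 0.32, and its test pointed down (adjusted p = 0.828). In the tryptophan pathway Ahr rose (1.81 ± 0.24) and Wars fell (-0.63 ± 0.22) among 7 genes (the same adjusted over the list alone), with a median of -0.19, a mean of 0.02 and an adjusted p of 0.725. Wars did not pass without naive replicate 2 or 3 or severe replicate 1 (adjusted p = 0.07, 0.0712 and 0.123 with limma) or with scaling on hybridization controls (0.362). Markers of other cells in the dissected tissue fell in part. Tfrc (-1.56 ± 0.21) and Alas2 (-1.51 ± 0.37) fell among 5 erythroid genes (adjusted p of the list 0.2), and Krt5 (-0.92 ± 0.23) and Krt10 (-0.64 ± 0.20) among 6 keratinocyte genes (0.369). Of 6 nerve and Schwann cell genes Mag (-1.07), Ncmap (-0.91 ± 0.27) and Mbp (-0.86 ± 0.25) fell and Pmp22 rose (0.83 ± 0.16), with an adjusted p of 0.494 for the list. In these 3 lists the counts adjusted over the list alone were the same. Of all 14309 genes 3277 were called lower in this comparison, and none of these lists passed. The counts therefore show no change particular to these cells. Other probe sets of Mbp were called higher. Krt10 did not pass without severe replicate 2 (adjusted p = 0.0558 with limma), nor Ncmap without naive replicate 2 (0.0553), and with scaling on hybridization controls neither did Krt10 (0.24), Ncmap (0.0657) or Mbp (0.0832).

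**Figure D2:**
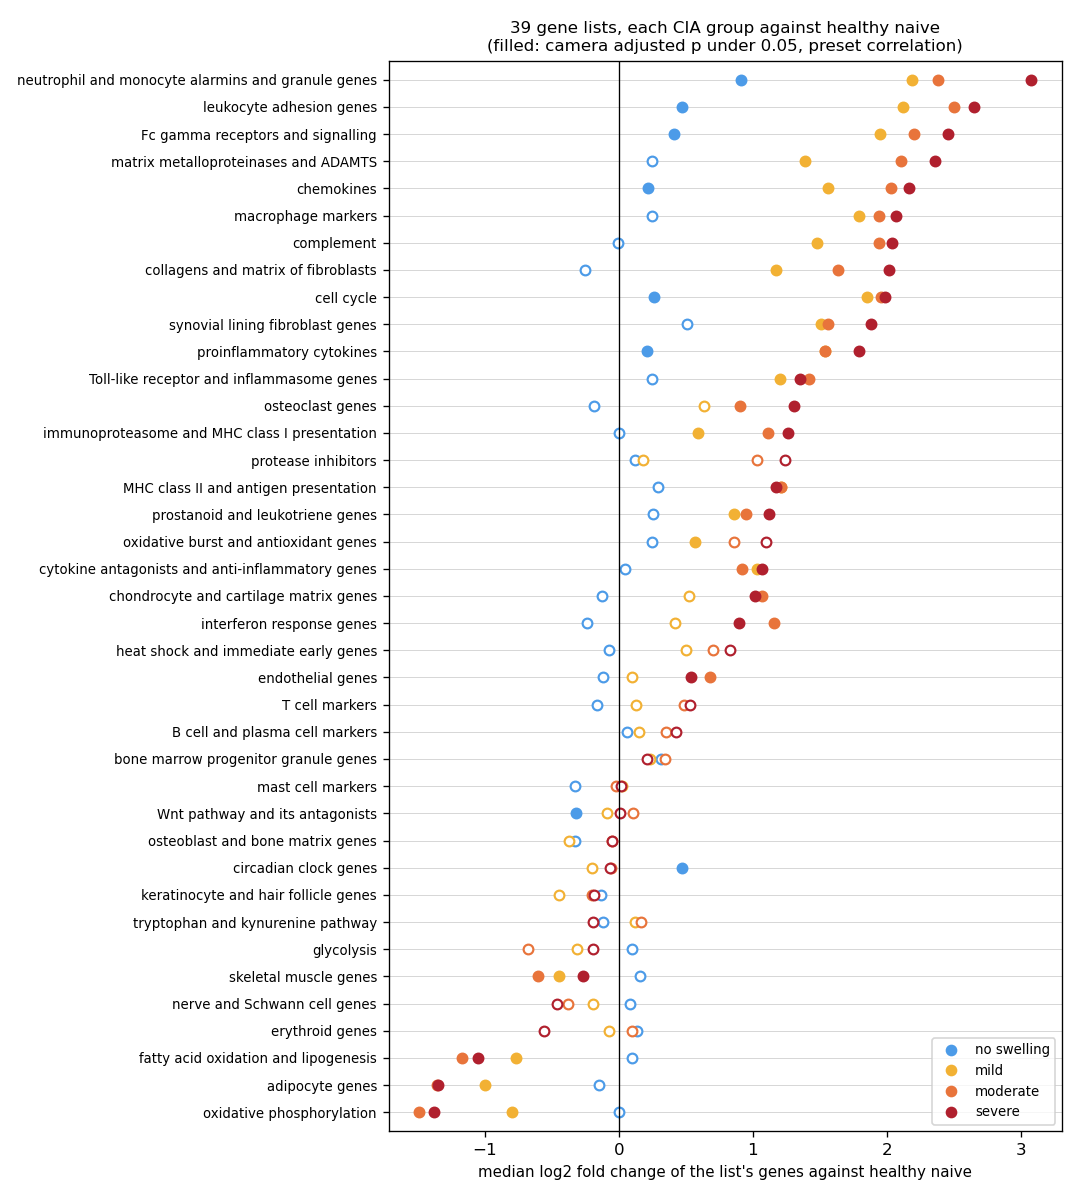
Median log2 fold change against naive joints (horizontal axis) of each of 39 gene lists (vertical axis) in the 4 CIA groups (colours), with filled points where the list's adjusted p passed with the preset correlation. With severe swelling the medians range from 3.08 for neutrophil and monocyte genes to -1.38 for oxidative phosphorylation; the mild median of skeletal muscle genes (-0.45) turns to 0.19 with scaling on hybridization controls, as do those of several lists with open points.

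Severe swelling against naive gave 7891 of 14309 genes past an adjusted p of 0.05 with limma, 4614 higher and 3277 lower, of which 2294 and 1279 changed at least 2-fold. 24 of 39 lists were called, 20 higher and 4 lower, and 0 of them kept the call with an estimated correlation. The share of higher calls was 58.5% as deposited, 47.2% with array medians aligned and 75.8% with arrays scaled on hybridization controls, bacterial and phage transcripts added before hybridization, a scaling chosen after seeing the data. The median over all genes was 0.11 as deposited, -0.05 with aligned medians and 0.30 with hybridization controls, so a change near these sizes has no settled direction. The medians of oxidative phosphorylation, adipocyte and fatty acid genes were -1.15, -1.12 and -0.82 with hybridization controls, and that of skeletal muscle genes was -0.03 against -0.27 as deposited.

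Moderate swelling against naive resembled severe swelling in its leading genes. Mmp13 (7.57 ± 0.73), S100a9 (6.72 ± 0.48), S100a8 (6.45 ± 0.54), Cxcl5 (6.44 ± 0.21), Saa3 (6.0 ± 0.29) and Slpi (5.69 ± 0.34) had the largest increases. Myl3 (-4.66 ± 0.67), Smox (-4.38 ± 0.31), Myl2 (-4.27 ± 0.76), Dhrs7c (-4.18 ± 0.40), Mettl21e (-4.12 ± 0.35) and Myh7 (-4.04 ± 0.88) had the largest decreases (n = 3 per group). In the gene lists, all 20 oxidative phosphorylation genes fell (20 adjusted over the list alone; median -1.49), 17 of 20 skeletal muscle genes fell (19 adjusted over the list alone). All 14 matrix metalloproteinase and ADAMTS genes rose (14 adjusted over the list alone), and 15 of 18 fibroblast matrix genes rose (15 adjusted over the list alone). These lists had adjusted p-values of 1.27e-11, 2.7e-05, 8.17e-07 and 8.73e-06, and the adjusted p = 0.256, 0.301, 0.256 and 0.342 with an estimated correlation. The muscle median was -0.60 as deposited, -0.14 with quantile normalization and -0.06 with hybridization controls. Sln, a regulator of the muscle calcium pump, rose by 3.24 ± 0.59. 24 lists were called, 20 higher and 4 lower, and with an estimated correlation their adjusted p lay between 0.256 and 0.352. In uncalled lists the median, mean and test differed in sign for mast cell (median -0.02, mean 0.51), erythroid (0.10, -0.41), tryptophan (0.16, 0.11, test down), clock (-0.06, 0.31) and Wnt genes (0.11, 0.35, test down). 7799 genes passed with limma, 4402 higher and 3397 lower, 2211 and 1242 of them by at least 2-fold. The share of higher calls was 56.4% as deposited and 87.7% with scaling on hybridization controls, where the median of all genes was 0.52 and 539 called genes changed sign.

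Mild swelling against naive showed the inflammatory genes already high. S100a9 (6.20 ± 0.48), Cxcl5 (5.91 ± 0.21), S100a8 (5.78 ± 0.54) and Saa3 (5.65 ± 0.29) rose most, followed by Il6 (5.34 ± 0.34) and Rrad (5.30 ± 0.43), a gene of a small GTPase (n = 3 per group). Myl3 (-3.01 ± 0.67), Bdh1 (-2.87 ± 0.54), Myl2 (-2.75 ± 0.76), Myh7 (-2.73 ± 0.88), Myh2 (-2.53 ± 0.74) and Fn3k (-2.44 ± 0.27) fell most. Without mild replicate 3, Myl2, Myh7 and Myh2 did not pass (adjusted p = 0.0548, 0.134 and 0.0822 with limma), and without naive replicate 2 Myh7 did not (0.0791). Of the lists, 18 of 23 chemokines (20 adjusted over the list alone), 17 of 18 cell cycle genes (17 adjusted over the list alone) and 14 of 16 macrophage markers (14 adjusted over the list alone) rose, and 19 of 20 oxidative phosphorylation genes fell (20 adjusted over the list alone). Their adjusted p-values were 2.24e-08, 1.17e-09, 9.36e-08 and 1.17e-09, and the adjusted p = 0.178, 0.178, 0.228 and 0.228 with an estimated correlation. 3 of 17 interferon response genes rose, Igtp (1.25), Oas1a (0.92 ± 0.18) and Oasl2 (0.59 ± 0.22; 2 adjusted over the list alone). That list did not pass (adjusted p = 0.115), but it did without naive replicate 1 (0.029) or mild replicate 2 (0.0297). The oxidative burst list passed here (adjusted p = 0.0411, 6 of 11 higher, 6 adjusted over the list alone; the adjusted p = 0.228 with an estimated correlation), and did not with other filters or array weights (0.0647 to 0.0876). Skeletal muscle genes fell in 11 of 20 cases (13 adjusted over the list alone). With camera the muscle list's adjusted p was 2.8e-05, and the adjusted p = 0.331 with an estimated correlation. Its median was -0.45 as deposited and -0.09 with quantile normalization, and turned to 0.19 with scaling on hybridization controls. In total 21 lists were called, 17 higher and 4 lower, and with an estimated correlation their adjusted p lay between 0.178 and 0.45. Median, mean and test differed in sign for glycolysis (median -0.31, mean 0.16), clock (-0.20, 0.23) and Wnt genes (-0.09, 0.12), none of them called. 5717 genes passed with limma, 3280 higher and 2437 lower (1346 and 458 by at least 2-fold). Higher calls made up 57.4% as deposited, 48.7% with array medians aligned and 97.3% with scaling on hybridization controls. With hybridization controls the median of all genes was 0.58 and 858 called genes changed sign.

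CIA joints without swelling were set against naive joints to ask what differs where no swelling is seen. S100a9 (3.73 ± 0.48), Serpinb1a (3.44 ± 0.29), an inhibitor of neutrophil proteases, Saa3 (3.42 ± 0.29), Rrad (3.39 ± 0.43), Dbp (3.29 ± 0.21), a clock-controlled transcription factor, and S100a8 (3.21 ± 0.54) rose most (n = 3 per group). Socs3 (3.06 ± 0.20), Il6 (2.80 ± 0.34), Mpeg1 (2.19 ± 0.33), Cxcl5 (2.0 ± 0.21) and Arg1 (1.97 ± 0.34) also rose, whereas Mmp13 (1.40 ± 0.73, adjusted p = 0.318 with limma) and Mmp3 (1.16 ± 0.37, 0.102) did not pass. The largest decreases were in Bdh1 (-2.35 ± 0.54), a ketone body enzyme, Tnni1 (-2.17 ± 0.56), the slow-fibre troponin I, the heat shock genes Hspa1a (-1.97 ± 0.24) and Hspa1b (-1.89 ± 0.18), Slc16a3 (-1.89 ± 0.27) and Tnfrsf12a (-1.84 ± 0.36). Tnni1 did not pass without naive replicate 1, 2 or 3 (adjusted p = 0.106, 0.152 and 0.111 with limma) or without no-swelling replicate 1 or 3 (0.194 and 0.156), nor in 6 other settings (0.0505 to 0.0715). Bdh1 did not pass without naive replicate 1, 2 or 3 (0.0871, 0.084 and 0.104) or no-swelling replicate 1 (0.115), nor Tnfrsf12a without naive replicate 1 or 3 (0.0534 and 0.0582).

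Of the lists, 8 were called without swelling, 7 higher and 1 lower, by the preset correlation. 6 of 15 neutrophil and monocyte genes rose (8 adjusted over the list alone), with Clec4d at 1.21 ± 0.23 and Csf3r at 1.23 ± 0.29 beside the alarmins, and the list's adjusted p of 1.5e-07 became an adjusted p = 0.324 with an estimated correlation. Il6, Il33 (1.25 ± 0.27) and Il1b (1.16 ± 0.25) rose among 13 cytokine genes (4 adjusted over the list alone; adjusted p = 0.00071, and the adjusted p = 0.324 with an estimated correlation). Cxcl5, Ccl7 (1.98), Ccl12 (1.74 ± 0.30) and Cxcl1 (1.24 ± 0.22) rose among 23 chemokines (7 adjusted over the list alone; adjusted p = 0.000628, and the adjusted p = 0.643 with an estimated correlation). Selp (1.51 ± 0.22) rose among 12 adhesion genes (3 adjusted over the list alone), Fcgr4 (1.08) among 11 Fc gamma receptor genes (2 adjusted over the list alone), and Birc5 (1.14 ± 0.28) and Mcm5 (0.96 ± 0.23) among 18 cell cycle genes (2 adjusted over the list alone). These 3 lists had adjusted p-values of 0.000404, 0.00721 and 0.00542, and each had an adjusted p = 0.643 with an estimated correlation. Of 13 clock genes Dbp, Ciart (2.33), Per2 (1.71), Per3 (1.54), Per1 (1.02 ± 0.16) and Nr1d2 (0.75) rose (7 adjusted over the list alone). Arntl (-1.70 ± 0.20), a core activator of the clock, fell (2 adjusted over the list alone). The clock list had an adjusted p of 6.52e-05 and an adjusted p = 0.324 with an estimated correlation. The Wnt list was lower (median -0.32, adjusted p = 0.0297, and the adjusted p = 0.324 with an estimated correlation), although 0 of its 10 genes passed (0 adjusted over the list alone). Heat shock and immediate early genes were not called as a list (adjusted p = 0.568), with Junb (1.79 ± 0.20) and Fos (1.31 ± 0.23) higher (4 adjusted over the list alone) and Hspa1a, Hspa1b and Dnajb1 (-0.94) lower (5 adjusted over the list alone). 0 of 20 oxidative phosphorylation genes passed with limma (0 adjusted over the list alone), and the list's median of 0.0011 turned to -0.17 with quantile normalization and -0.21 with scaling on hybridization controls. Median, mean and test differed in sign for that list and for those of muscle (median 0.16, mean -0.23), erythroid (0.13, -0.20), nerve (0.08, -0.005), glycolysis (0.10, -0.14), immunoproteasome (-0.0022, 0.11) and complement genes (-0.0025, 0.01), none of them called.

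**Figure D3:**
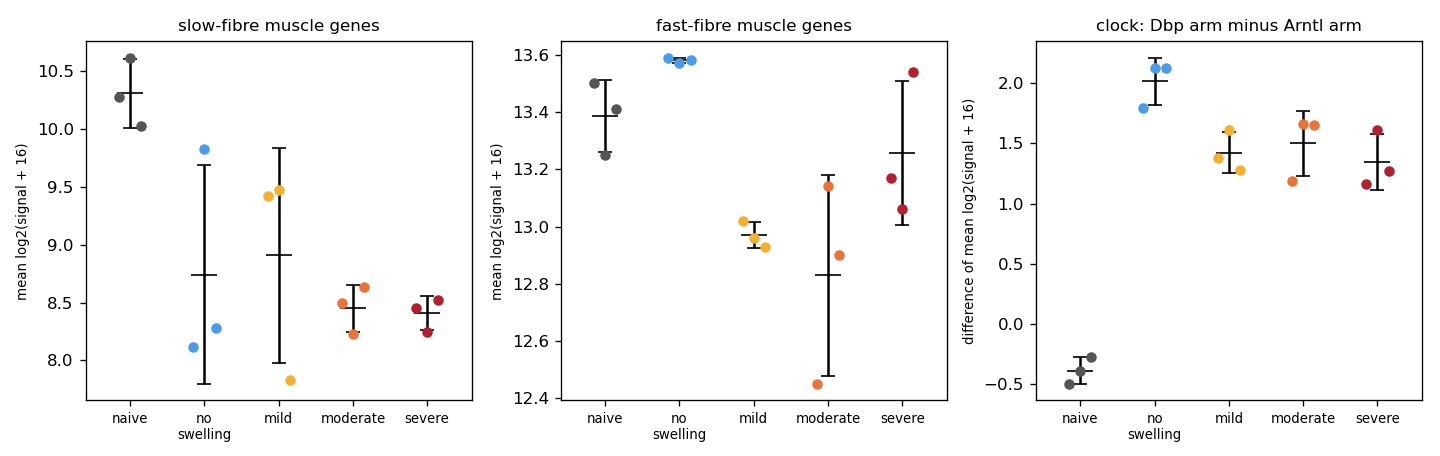
Mean log2(signal + 16) of 12 slow-fibre and 9 fast-fibre muscle genes, and the difference between 2 arms of clock genes (vertical axes), on each array (points) in the 5 groups (horizontal axes), with the mean (long line) and SD (bars) of 3 arrays. The slow-fibre mean is 10.3 in naive joints and 8.74 without swelling, the fast-fibre mean is 13.4 and 13.6 (its median change turns from 0.20 to -0.02 with scaling on hybridization controls), and the clock difference is -0.39 and 2.02; these lists were drawn up after seeing the data.

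Without swelling, 475 genes passed with limma, 217 higher and 258 lower (82 and 56 by at least 2-fold), and 2704 had an unadjusted p under 0.05. The count was 131 with scaling on hybridization controls, 313 with quantile normalization, 297 without an intensity trend, 1153 with default array weights and 1057 with weights estimated gene by gene. Leaving out naive replicate 1, 2 or 3 gave 154, 187 and 126 genes, and leaving out no-swelling replicate 1 or 3 gave 133 and 308. The lists called were 5 without no-swelling replicate 1 and 15 without replicate 3. The Fc gamma list did not pass without replicate 1 or 2 (adjusted p = 0.05 and 0.233), nor the cell cycle list without replicate 1 (0.0963), nor the Wnt list without replicate 1 or 3 or naive replicate 2 (0.05, 0.056 and 0.0761). The signal of the 5' probe set for 18S ribosomal RNA, a control, was 5868 ± 2510 (SD, n = 3) without swelling against 337 ± 263 in naive joints and moved with the genes called here. The share of higher calls was 45.7% as deposited, 50.5% with quantile normalization, 54.7% with array medians aligned and 26.7% with scaling on hybridization controls. The direction of the majority thus depended on the scaling. With hybridization controls the median of all genes was -0.18.

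Among the CIA groups, joints with and without swelling differed in many genes. From no to severe swelling, Mmp13 (5.90 ± 0.73), Mfap4 (5.42 ± 0.61), a gene of elastic fibres, Crabp2 (5.13 ± 0.55), which binds retinoic acid, Slpi (4.97 ± 0.34), Chil1 (4.97 ± 0.46) and C1qtnf3 (4.78 ± 0.43) rose most. Dhrs7c (-3.98 ± 0.40), Mlf1 (-3.62 ± 0.33), Fbp2 (-3.51 ± 0.31), Tlcd3b (-3.50 ± 0.33), Nmrk2 (-3.42 ± 0.24) and Lrrc38 (-3.27 ± 0.41) fell most (n = 3 per group). From no to mild swelling, the step at which swelling appears, Cxcl5 (3.90 ± 0.21), Ptgs2 (3.25 ± 0.29) and Cthrc1 (3.21 ± 0.52) rose most. Fn3k (-2.22 ± 0.27), Adipoq (-1.89 ± 0.50), the fat cell hormone adiponectin, and Ky (-1.89 ± 0.23) fell most. The 18S 5' control signal of the arrays without swelling (5868 ± 2510, SD, n = 3) lay apart from that with mild swelling (375 ± 154) on every array and above the severe mean (2502 ± 3240), so it moved with both comparisons. Severe against no swelling gave 7849 genes with limma, 4718 higher and 3131 lower, and mild against no swelling 5494, 3272 higher and 2222 lower. The shares of higher calls were 60.1% and 59.6% as deposited, 45.5% and 46.3% with medians aligned, and 86.0% and 99.6% with scaling on hybridization controls, where the medians of all genes were 0.50 and 0.78 (0.14 and 0.09 as deposited) and 269 and 1494 called genes changed sign.

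From mild to moderate swelling, Mmp13 (3.62 ± 0.73), Sln (3.59 ± 0.59) and Mfap4 (2.72 ± 0.61) rose most, and Tlcd3b (-2.51 ± 0.33), Dhrs7c (-2.45 ± 0.40) and Mlf1 (-2.32 ± 0.33) fell most (n = 3 per group). 943 genes passed with limma, 459 higher and 484 lower. The count was 28 in a fit of the 6 arrays alone, 291 with scaling on hybridization controls, 2135 with weights estimated gene by gene and 4560 with default array weights. Without mild replicate 1, 2 or 3 the count was 394, 196 and 2009, and without moderate replicate 1, 2 or 3 it was 597, 234 and 400. Mmp13 did not pass without mild replicate 2 or moderate replicate 2 (adjusted p = 0.0571 and 0.052), nor Mfap4 without moderate replicate 2 (0.0739), and in a fit of the 6 arrays alone Mmp13 (0.0644), Mfap4 (0.102) and Dhrs7c (0.0567) did not pass.

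Severely and moderately swollen joints differed in 0 genes with limma, while 884 genes had an unadjusted p under 0.05 and 715 would by chance. The lowest p-values were those of Tob2 (-0.64 ± 0.12), Zfhx4 (-0.75 ± 0.15) and Aars2 (-0.92 ± 0.19), each with an adjusted p of 0.744 (n = 3 per group). Of 3573 genes that changed at least 2-fold between naive and severe swelling, 3211 had a 95% interval of the severe minus moderate difference within 2-fold either way. Over these 3573 genes the slope of the moderate on the severe log2 changes was 0.966, and the median absolute difference was 0.14 on the log2 scale. With scaling on hybridization controls the median of all genes was -0.25 in this comparison.

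**Figure D4:**
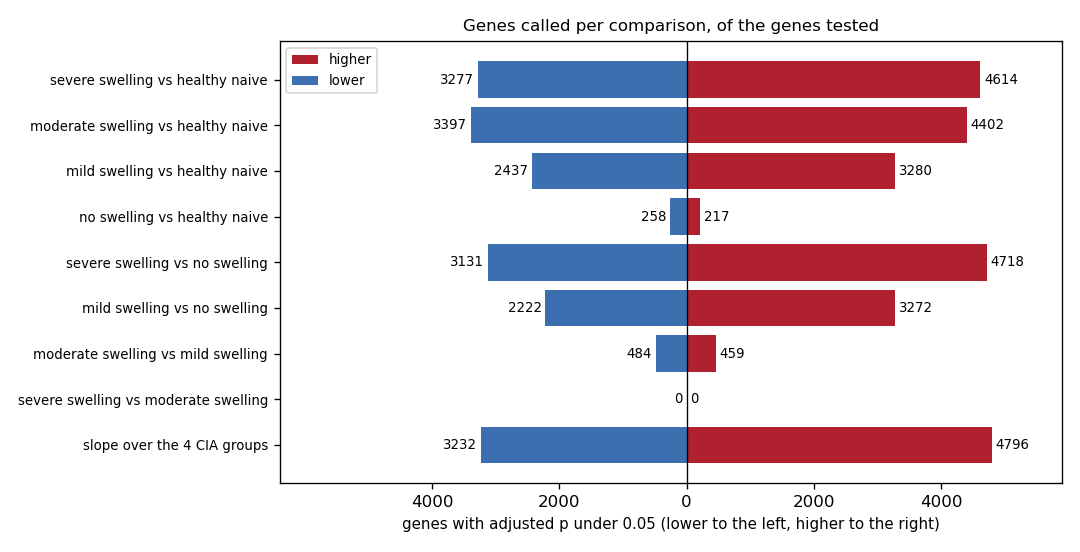
Number of genes past an adjusted p of 0.05 (horizontal axis, lower genes to the left and higher genes to the right) in each comparison (vertical axis), on the deposited scale. Severe swelling against naive has 4614 higher and 3277 lower genes, no swelling against naive 217 and 258, and severe against moderate swelling 0 and 0.

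A linear slope over the 4 CIA groups asks which genes follow the degree of swelling, with equally spaced grades. It can pass without a change at every step. The adjacent steps called 5494 genes from no to mild, 943 from mild to moderate and 0 from moderate to severe swelling. A called slope therefore does not show a graded response. Mmp13 (2.13 ± 0.23 log2 units per grade), Mfap4 (1.90 ± 0.19), Crabp2 (1.72 ± 0.17), Chil1 (1.71 ± 0.15), C1qtnf3 (1.63 ± 0.14) and Slpi (1.62 ± 0.11) had the steepest rises. Dhrs7c (-1.44 ± 0.13), Mlf1 (-1.32 ± 0.10), Tlcd3b (-1.30 ± 0.10), Fbp2 (-1.28 ± 0.10), Nmrk2 (-1.20 ± 0.08) and Lrrc38 (-1.18 ± 0.13) had the steepest falls (n = 12 arrays). 18 of 18 fibroblast matrix genes (18 adjusted over the list alone), 11 of 12 cartilage genes (11 adjusted over the list alone) and 10 of 13 osteoclast genes (11 adjusted over the list alone) rose with the grade, and 20 of 20 oxidative phosphorylation genes fell (20 adjusted over the list alone). Their adjusted p-values were 2.36e-07, 0.00368, 0.00301 and 1.08e-12, and each had an adjusted p = 0.318 with an estimated correlation. The 3' to 5' ratio of the actin control rose over the same groups (1.10, 1.16, 1.22 and 1.25, against 0.977 in naive joints) and so moved with the slope and with each comparison with naive. The clock list fell with the grade (8 of 13 genes, 8 adjusted over the list alone; adjusted p = 0.00585, and the adjusted p = 0.318 with an estimated correlation). The heat shock and immediate early list rose (10 of 14, 10 adjusted over the list alone; adjusted p = 0.0358, and the adjusted p = 0.428 with an estimated correlation), but did not pass without no-swelling replicate 3 (0.0558) or severe replicate 1 (0.0581). The muscle list fell (8 of 20 genes, 8 adjusted over the list alone; adjusted p = 0.00197, and the adjusted p = 0.428 with an estimated correlation), with a median of -0.12 that turned to 0.0088 with scaling on hybridization controls. The lining fibroblast list did not pass (adjusted p = 0.0595), but it did without mild replicate 2 (0.0415) or severe replicate 1 (0.0419). 25 lists were called, 20 higher and 5 lower, and with an estimated correlation their adjusted p lay between 0.318 and 0.428. Signs of median, mean and test differed for marrow granule (median 0.04, mean -0.02), osteoblast (0.02, 0.04, test down), keratinocyte (0.0074, -0.02), glycolysis (-0.15, 0.03) and tryptophan genes (-0.01, 0.01), none of them called. 8028 genes passed with limma, 4796 higher and 3232 lower, and 8664 differed among the 5 groups in any way by the moderated F test. The share of higher calls was 59.7% as deposited, 46.7% with medians aligned and 82.8% with scaling on hybridization controls, where the median of all genes was 0.14 and 163 called genes changed sign.

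Mild, moderate and severe swelling shared many of their changes against naive joints, and joints without swelling fewer. Severe and moderate swelling had 4002 higher and 2878 lower genes in common, where independent lists would share 1419 and 778, and 0 were called in opposite directions. Severe and mild swelling shared 3006 higher and 2173 lower genes (1058 and 558 by independence) with 9 opposite, and severe and no swelling shared 152 and 157 (69.97 and 59.1 by independence) with 47 opposite. Across genes, which are not independent replicates, the log2 fold changes of severe swelling correlated with those of moderate, mild and no swelling at 0.969, 0.912 and 0.359, with covariances of 0.92, 0.648 and 0.126. Unchanged groups were simulated with simulated naive arrays that all comparisons shared, and with genes varying independently. They gave correlations of 0.501, 0.498 and 0.502, covariances of 0.025, 0.0248 and 0.025, and 0 shared calls. With no real change few or no genes are called, so these 0 shared calls set no benchmark for the shared counts. The measured correlation of severe with no swelling lay under the simulated one, and its covariance lay above. Sharing control arrays of equal spread sets the simulated correlation near 0.5 in advance, so the lower correlation decides nothing. The simulated covariance leaves out deviations that many genes of an array share. Part of the excess covariance may come from the shared naive arrays, since 3 arrays are too few to split. The overlap of severe and no swelling, 309 genes, was 115, 137 and 94 without naive replicate 1, 2 or 3, and 95 without no-swelling replicate 1.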

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

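All tests in this part were chosen after the result was seen, except the test of slopes on 18S within the swollen groups, which was written before.

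Among 64 control probe sets, which no comparison used, a signal stood out where all 3 arrays of a CIA group lay above every naive array and their mean was at least 2-fold the naive mean. The 5' probe set for 18S ribosomal RNA had 17.4 times the naive signal without swelling (5868 ± 2510 against 337 ± 263, SD, n = 3), or 31.0 times without naive replicate 2. Its 3' probe set had 6.16 times the naive signal in severe swelling (1943 ± 2130 against 316 ± 133), but 2.27 times without severe replicate 3, which carries most of it. The probe set for the murine B1 repeat had 2.14, 2.80 and 2.84 times the naive signal of 837 ± 69.1 in mild, moderate and severe swelling. A bacterial control probe set for the dap gene had 2.31 times the naive signal in mild swelling, at signals of 1.23 ± 0.153 and 0.533 ± 0.404, close to 0 (4.11 times without naive replicate 3). With 256 pairs of a probe set and a group examined, some would stand out by chance, as 3 arrays would lie above 3 others.

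The 475 genes called without swelling against naive coincide with the high signal of the 5' 18S probe set on those arrays. Its log2 signal was 12.4 against 8.08 in naive joints, while mild arrays are near naive ones (8.45). The middle 18S probe set had mean signals of 327 without swelling, 166 in naive and 368 in severely swollen joints. The 3' probe set had 542, 316 and 1943. Only the 5' probe set had its highest group mean without swelling. Ribosomal RNA carried into the labelling is argued against as the whole cause of the 217 higher calls. Their change with mild swelling was a median of 1.13 times that without swelling (1.01 to 1.22 on single mild arrays). For groups of equal and independent spread, sharing the naive arrays gives 0.5. A deviation of the naive arrays alone would give more, so the ratio does not show that mild joints themselves changed. The 95% bootstrap interval was 0.909 to 1.38, and the median was 0.974 to 2.54 under the other scalings. For the 258 lower calls ribosomal RNA as the whole cause stays open, with a median of 0.702 (0.639 to 0.8) that turned to -0.0306 with hybridization controls. Both intervals resample genes and hold no spread between arrays. A partial share of ribosomal RNA also stays open, since 56.2% of the calls had a slope on 18S within the swollen groups with the sign of their change, against a median of 50.7% and a 95th percentile of 65.1% over 1000 permutations. The change of swollen joints at a lower degree stays open too: 41.1% of the calls moved further the same way with mild swelling (53.9% of the higher and 30.2% of the lower ones; 21.3% were called the same way and 29.1% the opposite way), and the shared arrays push this share down.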

How the results depend on the processing

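Scaling on hybridization controls and array weights estimated gene by gene were the alternatives chosen after seeing the data. Gene counts stayed within 1.5 times the value in 181 of 214 cases, counts of called lists in 102 of 111, and overlaps in 55 of 63. Named genes kept their direction and side of the threshold in 4148 of 4203 cases (42 no longer passed, 12 newly passed, 1 reversed) and lists in 4112 of 4319 (126 no longer passed, 81 newly passed). Many named genes were picked from these same data for large changes or low p-values, so their share says little about other genes. Mbp in severe swelling against naive turned to 0.039 with the mean of its probe sets, some of which were called in opposite directions. Testing every probe set by itself, which tests more items, gave 15610, 15513, 10867 and 867 for severe, moderate, mild and no swelling against naive, 15255 and 9974 for severe and mild against no swelling, 1487 and 1 for the next steps, 15675 for the slope and 17320 for any difference. Quantile normalization gave 313 genes without swelling against naive, and no intensity trend 297, with an overlap of severe and no swelling of 204. Default array quality weights, whose fit did not converge and gave mild replicate 1 a weight of 24.9, gave 9265 genes for mild and 1153 for no swelling against naive, 4560 for moderate against mild, and an overlap of 676. Weights estimated gene by gene gave 1057, 2135 and 612 for no swelling, moderate against mild and that overlap. Hybridization controls gave 131, 291 and 83 for these, and 17 lists without swelling. Only the groups compared gave 28 genes for moderate against mild, with fewer arrays. An estimated correlation left 0 lists in all 5 comparisons, and fry gave 4 without swelling. Leaving out 1 array gave 126 to 549 genes for no swelling against naive, 196 to 2009 for moderate against mild, 0 to 2 for severe against moderate, 6980 to 7687 for severe, 6979 to 7209 for moderate and 4327 to 6145 for mild against naive, 6836 to 7790 and 4085 to 5870 for severe and mild against no swelling, 7114 to 8041 for the slope, 8029 to 8873 for any difference, 5 to 15 lists without swelling, 24, 24 and 21 to 22 with severe, moderate and mild swelling, 24 to 26 for the slope, and overlaps of severe with moderate, mild and no swelling of 6176 to 6653, 3998 to 5580 and 94 to 320. Where 1 array of a group is left out, fewer arrays test each gene; for the other settings the cause was not tested.

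The replicate number as a block gave 300 genes without swelling against naive, and moved no other count of genes or lists by over 1.5 times. The numbers were not taken to pair the samples: of 30 correlations between same-numbered arrays' deviations from their group means, from -0.503 to 0.333, 5 were over 0.1. For no and moderate swelling all 3 were (0.15, 0.333 and 0.19), and each of these arrays correlated best with its own number, a hint from the data alone; in the other 9 pairs of groups this did not hold. Signals near the background limit the dim genes, whose log2 changes depend on the pseudocount.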

Other observations

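All tests of the muscle and clock genes in this part were chosen after the result was seen; the counts over other splits of the arrays were written before.

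Of 12 slow-fibre genes, listed after seeing the data, 9 fell in severe swelling (median -1.69) and 3 without swelling (-1.94), whereas 9 fast-fibre genes had medians of -0.16 and 0.20, which turned to 0.07 and -0.02 with scaling on hybridization controls. With moderate and mild swelling 10 and 9 of the slow-fibre genes fell (-1.71 and -1.54), and 7 and 4 of the fast-fibre genes (-0.56 and -0.41; -0.08 and -0.02 with quantile normalization, -0.02 and 0.23 with hybridization controls). Of 24 other muscle genes, 20 fell in severe swelling (median -1.28) and 0 passed with limma without swelling (median 0.06; -0.01 with quantile normalization and -0.15 with hybridization controls). For the clock, an arm of 8 genes with Dbp and an arm of 5 with Arntl were drawn up after seeing the data; they add Bhlhe41, Npas2 and Nfil3 to the clock list fixed before and leave out its members Cry2, Nr1d1 and Hlf. In severe, moderate, mild and no swelling 5, 5, 6 and 6 of the Dbp arm rose and 2, 2, 1 and 0 fell (in severe and moderate swelling Tef and Bhlhe41 fell), and 4, 3, 3 and 3 of the Arntl arm fell and 0 rose. The mean of the first arm minus that of the second was -0.39 ± 0.11 (SD, n = 3) in naive joints, 2.02 ± 0.20 without swelling, and 1.42 ± 0.17, 1.5 ± 0.27 and 1.35 ± 0.24 with mild, moderate and severe swelling.

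A signal ceiling that hides a loss of all muscle is argued against without swelling, where muscle genes with a naive log2 signal under 12 had a median change of 0.0464 (95% bootstrap interval -0.21 to 0.263). In severe swelling it stays open, since they had a median of -1.30 (-1.84 to -0.582). A smaller amount of muscle as a whole in the dissections is argued against without swelling, where all 24 other muscle genes had a median of 0.0634 (-0.000348 to 0.242), and stays open in severe swelling (-1.28, from -1.63 to -0.786). Different muscles, richer or poorer in slow fibres, stay open: the slow-fibre mean ranged over 1.72 without swelling, which is 0.902 of the severe minus naive difference (-1.90), but over 0.59, 1.64, 0.402 and 0.279 in naive, mild, moderate and severe arrays, and a spread between single arrays decides nothing. A fibre change that grows with swelling also stays open. The slow-fibre genes had a median slope of -0.0846 per grade (-0.398 to 0.112), which turned to 0.03 with scaling on hybridization controls. All these intervals resample genes and hold no spread between arrays. On single arrays the log2 mean of the 24 other muscle genes was 11.27 to 11.5 without swelling, against 11.19 to 11.3 in naive joints. In severely swollen joints that mean was 9.957 to 10.57. With limma, 0 of the 15 genes under 12 fell without swelling, and 12 fell in severe swelling. What is argued against therefore holds only for these arrays on the deposited scale.

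The clock difference lay above every naive array on 12 of 12 CIA arrays, but the arms were drawn up after this shift was seen, so the count does not decide. Another time of day at collection of the naive joints and an effect of immunization that does not depend on swelling predict the same and stay open. Over the CIA groups the difference fell, with a slope of -0.194 per grade (permutation p = 0.0163, two-sided, 100000 permutations, 12 arrays). The fall lay at the step from no swelling (2.02) to mild swelling (1.42), with 1.5 in moderate and 1.35 in severe swelling. These arms thus showed no rise with the grade of swelling. An effect that grows with joint inflammation is not decided by this slope, since the arms were drawn up after seeing the data. The fall also rests on the group with the high ribosomal RNA control signal.

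For 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split called 7891 genes for severe, 7799 for moderate and 5717 for mild swelling against naive, each the most of its splits (1 of 10), with 0 in the highest other. For no swelling against naive the real count was 475 and the highest other 1 (1 of 10). Severe and mild against no swelling gave 7849 and 5494 with 0 and 3 in the highest other, and moderate against mild 943 with 1. For severe against moderate swelling the real count was 0, which all 10 splits reached, and 1 split called 281, which points to a structure of the 6 arrays other than their group. That split, moderate replicates 1 and 3 with severe replicate 2, follows the second principal component (-9.96, -8.55 and -8.89 against 13.8, 21 and 18.4). It also parts the arrays with the lower log2 signals of hybridization controls (10.46, 11.06 and 11.04) from those with the higher ones (11.23, 11.18 and 11.66). These partings were seen afterwards, and the cause of the split was not tested. List counts were 24, 24, 21 and 8 for severe, moderate, mild and no swelling against naive, with 21, 23, 18 and 18 in the highest other split, and 4 of 10 splits reached the 8 without swelling. Over 100 groupings of the CIA arrays, the real one included, only the real one reached the slope's 8028 genes (highest other 7092). Over 100 groupings of the 15 arrays, again with the real one, only the real one reached the 8664 genes of any difference (highest other 4779). Each is a share of 1 in 100 among these arrays. Since replicates may not be separate animals, chance between animals is not excluded. The slope's 25 lists were reached by 9 of 100 groupings (highest other 27), so chance is not excluded for that count.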
